A study of Mus musculus with 9 samples.

How the data were processed

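Total RNA from mouse hearts was labelled with Cy3 and hybridised to a one-colour Agilent mouse long non-coding RNA array. Scanner images were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The deposited value table holds log2 intensities for 91200 probes, from 1.27 to 18.6. Its arrays share nearly the same distribution (largest difference between arrays at the quantiles checked 0.0011), as quantile normalization gives, and the normalization tool is not given in the sources used here. The deposited table of the authors' own comparison gives, per the file headers, log2 values, detection calls, p-values, -log10 p-values and signed fold changes for 128 probes. Its values equal those of the value table (largest difference 5e-09), and its p-values equal an equal-variance two-sample test on them (largest difference 3e-10).

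Groups were taken from the labels. The 4 sedentary and 5 swimming arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on the values as deposited, over all probes, with a Benjamini-Hochberg adjusted p under 0.05. This test, the rule for named genes and the other settings tried, apart from those said to be chosen later, were fixed before the data were examined. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9. On data simulated for this comparison of 91200 probes with 200 changed, the fit recovered 2%, 20%, 48% and 58% of the probes changed by 0.5, 1, 1.5 and 2 on the log2 scale, and called 5 unchanged probes. With 5000 changed it recovered 17.8%, 45.6%, 71.4% and 82%, and called 154 unchanged probes. The simulated noise was normal and independent between probes, without differences that whole arrays share. These shares and counts therefore need not hold for the real arrays.

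Only 67 probes carried a symbol, all in the authors' deposited table, and the GAPDH and PGK1 probes carry theirs in the probe name. Of the 67, 51 matched the gene table used. The named genes are those with 1 symbol, an adjusted p under 0.05, groups that do not overlap and a mean in the higher group of at least 3.59, the median of all probe means: up to 12 per direction by size, filled to 12 by smallest p and then given as values. Added to these are measured members of the fixed gene lists, 2 unnamed probes per direction, and the first 3 names per direction of the authors' deposited table. Of 40 fixed lists, 2 had a measured member and 0 had the 3 needed for a set test, so the planned test of gene lists and the cell type marker lists were not run.

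Detection calls were used for listed probes. Where a probe was detected on no array of a group, the fold is given as at least a value. That value sets the brighter group's mean against a mean over the dimmer group's arrays. Each of those arrays counts as the higher of the lowest detected signal among the listed probes and the probe's own signal. Detection limits that differ between probes and the spread between hearts are not allowed for, so these folds are bounds on the measured means only. Alternatives were other normalization, filters on dim probes, other variance models, array weights, the replicate number as a block, and leaving out each array. The labels give both groups the same heart numbers and do not say that a number marks a shared litter, cage or day. Each array was taken as 1 mouse, as the design text counts them.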

Results

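The data are one-colour microarray measurements of RNA from whole hearts of male mice aged 11 weeks. Sedentary mice were set against mice that swam for 3 weeks, in 2 sessions a day that lengthened from 10 min to 90 min, a protocol the labels describe as a way to induce physiological growth of the heart. The array is an Agilent design for mouse long non-coding RNAs, and 4 sedentary hearts (11, 12, 14 and 15) and 5 swimming hearts (11 to 15) were analysed. A sedentary heart 13 was not analysed here. The values are normalized log2 intensities for 91200 probes, and the array medians lie between 3.77 and 3.771. The number of arrays limits the precision, and the labels name no slide or scan batch. The comparison asks which RNAs differ in the heart after swimming training.

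RNAs of the glycolytic enzymes GAPDH (glyceraldehyde-3-phosphate dehydrogenase) and PGK1 (phosphoglycerate kinase), both often used as reference genes, gave higher signal in swimming hearts. Mouse-PGK1_3 rose from 8.95 ± 0.11 (SD, n = 4) to 9.81 ± 0.22 (SD, n = 5), a 1.82-fold difference (limma adjusted p = 0.018). Mouse-GAPDH_3 rose from 12.45 ± 0.19 to 13.25 ± 0.09, a 1.73-fold difference (limma adjusted p = 0.0216). The remaining mouse probes, Mouse-GAPDH_5 and Mouse-PGK1_5, rose 1.59-fold and 1.41-fold (limma adjusted p = 0.0418 and 0.0397). None of the 4 probes passed when any 1 sedentary heart was left out (limma adjusted p = 0.0507 to 0.117) or without a mean-variance trend (0.0523 to 0.1), while their differences on the log2 scale stayed between 0.45 and 0.92 in all settings run. These 4 probes measure 2 of the 23 genes on the glycolysis and glucose uptake list. Adjusted over these 4 alone, their largest limma adjusted p was 0.000504. That adds no support, since all 4 had already passed over all probes. Of 8 human and rat probes for the same genes, 4 were higher past the threshold and 0 were lower. The array names tell the probes of a gene apart by the endings _3 and _5, whose meaning is not given in the sources used here.

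**Figure D1:**
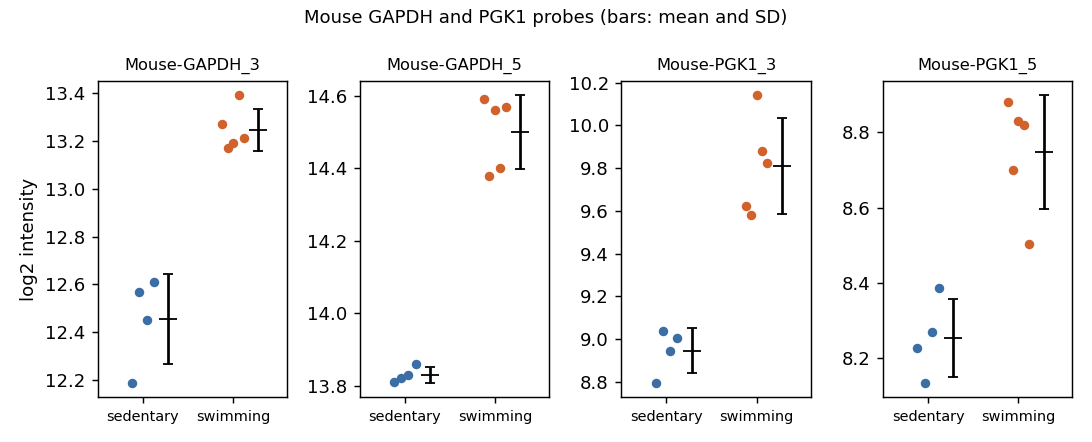
Log2 intensity of the 4 mouse GAPDH and PGK1 probes in each heart, with group mean and SD; each panel has its own axis, which does not start at 0. In each panel the 5 swimming values lie above the 4 sedentary values, by 0.79, 0.67, 0.86 and 0.49 on average from left to right.

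Among non-coding records with a gene symbol, BC020402 and Gm9899 rose from signals that were not detected in sedentary hearts. Gm9899, a long non-coding RNA, was not detected on any of the 4 sedentary arrays and was detected on all 5 swimming arrays, so that it was at least 1.89-fold higher (limma adjusted p = 0.0219). BC020402 was detected in 0 sedentary and 4 swimming hearts and was at least 1.63-fold higher (limma adjusted p = 0.0319). Atcayos, a long non-coding RNA that overlaps Atcay and the nicotinamide riboside kinase gene Nmrk2, rose from 4.45 ± 0.50 to 5.98 ± 0.08 (SD, n = 4 and 5), a 2.88-fold difference, and was detected in 3 of 4 sedentary hearts. Non-coding records placed at 3 protein-coding genes also rose, at R3hdm1, at Car5b (a mitochondrial carbonic anhydrase) and at Ccdc50. They were detected in all 5 swimming hearts but in only 1, 2 and 3 of the 4 sedentary hearts, so that their measured differences of 1.68, 1.48 and 1.33 on the log2 scale rest partly on signals that were not detected. The authors' deposited table types these records as non-coding, and whether their probes also read the messenger RNAs of those genes was not tested. 2210017G18Rik, detected in all 9 hearts, rose 2.39-fold. 5330421F21Rik and 4933406F09Rik rose as well, but each was detected in only 1 sedentary heart, and no fold is given for them. Each rise named here missed the adjusted threshold when sedentary heart 11 or sedentary heart 14 was left out, and also without a mean-variance trend.

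The largest fall among symbol-bearing records past the threshold was in Gm15834, a long non-coding RNA that overlaps Fam126b. It went from 8.28 ± 0.24 (SD, n = 4) to 6.50 ± 0.41 (SD, n = 5), 3.45-fold lower (limma adjusted p = 0.0139). Pitpnm2os2, which overlaps the phosphatidylinositol transfer gene Pitpnm2, was 2.48-fold lower, and Gm26844 was 2.47-fold lower. A non-coding record placed at Sgcb, the gene of beta-sarcoglycan in the muscle membrane complex, was 2.75-fold lower (limma adjusted p = 0.0411). Rbm46os and the record at the zinc finger gene Zfp719 were not detected on any swimming array and were at least 1.61-fold and at least 1.3-fold lower. 4930555O08Rik, the pseudogene Hmga2-ps1 and Gm14968 were 2.43-fold, 2.42-fold and 2.35-fold lower. All of these falls also missed the adjusted threshold when sedentary heart 11 or sedentary heart 14 was left out, and without a mean-variance trend. Neighbouring and overlapping genes were read from a gene table of the GRCm38.p6 assembly, and the authors' deposited table names no build. That table places Gm9899 on chromosome 5 from 30577468 to 30578024, BC020402 on chromosome 10 from 7678971 to 7681158, Gm15834 on chromosome 1 from 58505148 to 58523232 and H19 on chromosome 7 from 142575536 to 142578144, with positions stored to limited precision.

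**Figure D2:**
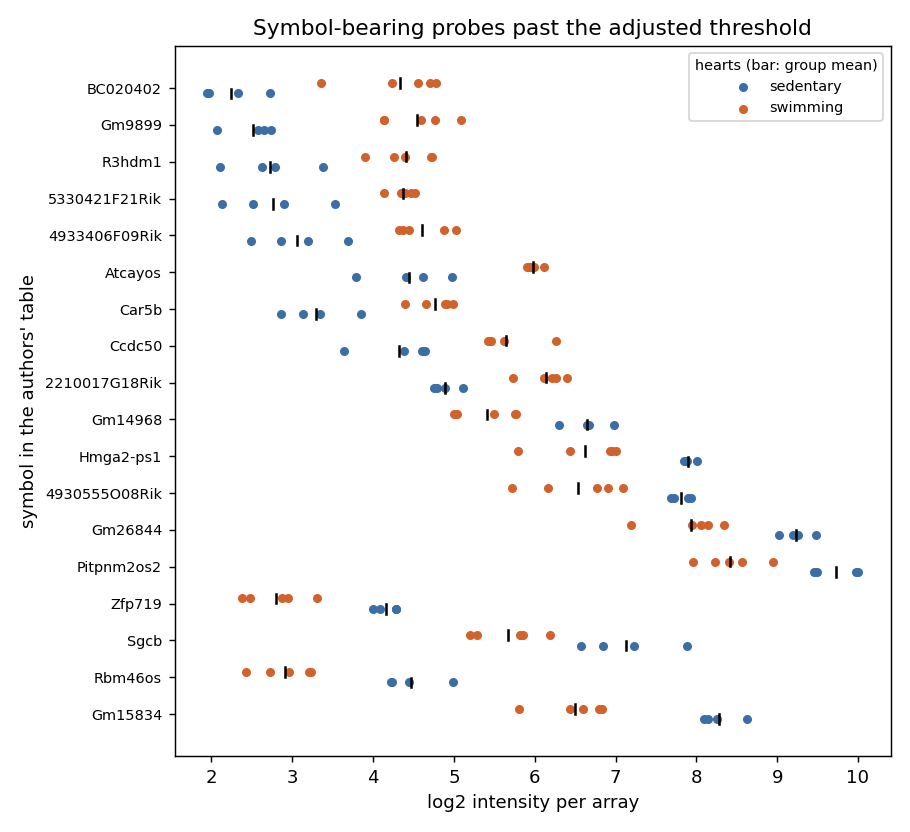
Log2 intensity per heart for the 18 symbol-bearing probes past the threshold, with group means as bars. The 9 probes at the top are higher in swimming hearts and the other 9 lower, and the groups do not overlap for any of the 18, as the choice of these probes required.

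H19, an imprinted long non-coding RNA beside Igf2, had a mean of 6.37 ± 0.30 (SD, n = 4) in sedentary and 8.81 ± 1.43 (SD, n = 5) in swimming hearts, without passing the threshold (limma adjusted p = 0.0806). Its value in swimming heart 13 was 11.2, and without that heart the difference was 1.83 on the log2 scale with a limma adjusted p of 0.0239. A non-coding record at Hlf, a transcription factor gene of the clock output list, differed by 1.61 (limma adjusted p = 0.0673), with detection in 2 of 4 sedentary hearts. One at Dcn, a fibroblast gene, was detected in 4 sedentary hearts and 0 swimming hearts, with a sedentary mean at least 1.57-fold above the swimming hearts (limma adjusted p = 0.0894). The records at Ccnt1, detected in 3 sedentary hearts, and C78859 differed by 1.21 and 1.26, also without passing. Without swimming heart 13 the difference of C78859 was 0.96 and passed (limma adjusted p = 0.021). 4930402M22Rik, C030006F08Rik and Gm13817 did not pass either and were detected in 0 swimming hearts, with sedentary means at least 1.22-fold, 1.55-fold and 1.29-fold above the swimming hearts. Gm12665, 1700040B14Rik and C730014E05Rik, the first lower names in the authors' deposited table, did not pass (limma adjusted p = 0.108, 0.114 and 0.0681). Gm12665 and 1700040B14Rik were detected in 3 sedentary hearts and 0 swimming hearts, with sedentary means at least 2.39-fold and 2.03-fold above the swimming hearts. Without sedentary heart 12, in which neither was detected, Gm12665 passed (limma adjusted p = 0.0495) and 1700040B14Rik did not (0.0521). C730014E05Rik was detected in 4 sedentary hearts and 1 swimming heart. Of these 11 named probes that did not pass, 9 passed once the lowest 30% of probes were left out, among them H19 (limma adjusted p = 0.038), Hlf (0.0329) and Dcn (0.0463), and Gm12665 and 1700040B14Rik did not.

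Over all 91200 probes, 987 were higher and 512 lower in swimming hearts (limma, Benjamini-Hochberg adjusted). The excess of higher calls lay in probes with IDs that begin with A (814 higher, 300 lower); of those that begin with mmu, the class of 127 of the authors' listed probes, 165 were higher and 212 lower. The median size of these 1499 differences was 1.68-fold, and 307 reached 2-fold. Groups did not overlap for 1497 of them and for 10.3% of all probes, where chance gives 1.59%. Among probes without a symbol here, A_51_P241319 and A_51_P159453 were higher and A_55_P2101177 and mmu_1044_PI428960544 lower in swimming hearts. Detection calls for these probes were not analysed here, so each dim value was raised to the lowest detected signal of the listed probes on its array. A_51_P241319 and A_51_P159453, under that level in all 4 sedentary hearts, were then at least 3.22-fold and 2.81-fold higher. mmu_1044_PI428960544, under it in all 5 swimming hearts, was at least 2.54-fold lower. A_55_P2101177, under it in 1 swimming heart, was 15.5-fold lower both as measured and after that step, so this fold is not a lower bound. Its log2 values were 8.5 to 9.72 in sedentary hearts, 6.84 and 6.68 in swimming hearts 14 and 15 and 3.9 to 4.5 in the other swimming hearts. Without swimming hearts 14 and 15 its difference went from -3.95 to -4.95. The count of calls depended strongly on the variance model and on single arrays: 5 probes passed without a mean-variance trend, and 7, 34, 5 and 202 passed without sedentary hearts 11, 12, 14 and 15 in turn. Leaving out swimming hearts 11 to 15 in turn gave 485, 579, 1125, 752 and 421.

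Swimming hearts 14 and 15 stood apart from the other swimming hearts. Their correlations with swimming hearts 11, 12 and 13, across probes, were 0.937 to 0.946, against 0.963 to 0.972 among those 3. With sedentary heart 12 those 3 correlated at 0.952 to 0.966. The sedentary hearts divided as well. Sedentary hearts 12 and 14 correlated at 0.9604 to 0.9659 with swimming hearts 11 and 12, and at 0.9501 to 0.9531 with sedentary hearts 11 and 15. The median correlation was 0.946 within swimming hearts, 0.952 within sedentary hearts and 0.945 between the groups. With swimming hearts 14 and 15 left out, a refit chosen after seeing the data called 1310 probes higher and 1751 lower. Of these calls 42.8% were higher, against 65.8% with all arrays. Of the 1499 calls with all arrays, 993 were called again.

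**Figure D3:**
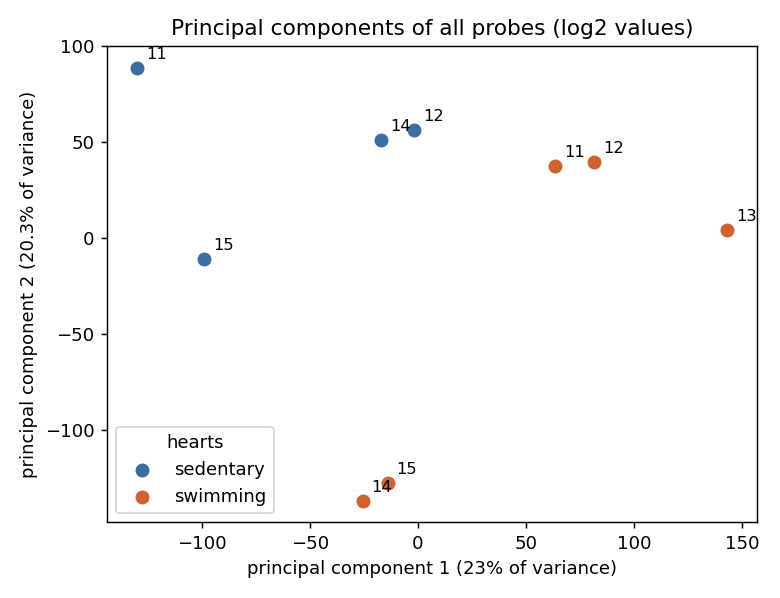
First and second principal components of the log2 values of all probes, which hold 23% and 20.3% of the variance; each point is a heart, numbered within its group. Swimming hearts 14 and 15 lie at -137 and -128 on the second component, and the other swimming hearts between 3.92 and 39.4. On the first component sedentary hearts 11 and 15 lie at -130 and -98.7, and sedentary hearts 12 and 14 at -1.64 and -17.1.

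The authors' deposited table lists 128 non-coding probes, 70 higher and 58 lower in swimming hearts, each differing by at least 2.3-fold. Of the 67 with a symbol, 19 belong to long non-coding genes, 31 are placed at protein-coding genes, 1 at a pseudogene and 16 were not matched in the gene table. The limma fit over all probes passed 32 of the 128, of which 19 were higher and 13 lower. The largest p in the authors' deposited table is 0.0222, beside an adjusted value of 0.0495. The set of probes over which it was adjusted is not given in the sources used here. For a Benjamini-Hochberg adjustment of the same test, these values allow at most 21802 probes in that set, fewer than all 91200. The same equal-variance test adjusted over all 91200 probes passed 11 of the 128. The list was chosen on these samples, so its directions are not independent evidence.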

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

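Of the tests in this part, the counts of other splits past the adjusted threshold were chosen before their result was seen, and the others only after it.

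Single hearts lay far from the rest of their group for 5 of 74 groups of probes given by name or by probe ID alone, where chance gives about 3.7. Gm12665 had 1.43 in sedentary heart 12 against 5.91 to 6.43 in the others (gap over range 0.895). 1700040B14Rik, not detected in any swimming heart, had 2.04 in swimming heart 15 against 1.39 to 1.56 (0.746). Swimming heart 13 was highest for the records at Hlf, with 6.63 against 5.11 to 5.52 (0.732), at Ccdc50, with 6.26 against 5.42 to 5.62 (0.77), and at C78859, with 8.78 against 7.04 to 7.47 (0.756).

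The number of probes past the threshold was set against other groupings of the hearts. Of 100 splits into 4 and 5 hearts, 1, the real one, gave as many as 987 higher probes, and the highest other gave 1. For the 512 lower probes it was again 1 of 100, with 0 in the highest other. That is the smallest share 100 splits can give, so it argues against chance alone but cannot exclude it. At an unadjusted p under 0.05 (limma) the contrast was smaller, with 16323 probes in the real split and 13067 in the highest other. A refit over all probes without swimming hearts 14 and 15 called 3061, which argues against these hearts carrying the count. An earlier form of this test asked whether the 1499 called probes kept an unadjusted p under 0.05 without both hearts; all did, but they had been picked at a p of at most 0.00082, so it could hardly fail and was set aside. What sets these 2 hearts apart, and whether it reflects training, was not tested.

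The rise of the mouse GAPDH and PGK1 probes was set against probes of like brightness. Their median differences were at most -0.0626, so they did not rise as a whole. Mouse-GAPDH_3, Mouse-GAPDH_5, Mouse-PGK1_3 and Mouse-PGK1_5 lay at percentiles 92.6, 92.7, 98.6 and 89.6 among them, so some probes of like brightness rose more. A cause that raises only the _3 probes would leave the _5 probes in place, and they rose by 0.582 (SE 0.0508). The _3 probes rose by 0.245 more (exact permutation p = 0.0317). That was 0.37 for PGK1 and 0.119 for GAPDH (exact permutation p = 0.0556 and 0.365), so such a part of the rise stays open. Whether such a cause would be a loss of RNA integrity cannot be told, since the meaning of the endings is not given in the sources used here. The probes of other species split. The human _3 probes differed by 1.11 (GAPDH) and 0.47 (PGK1) against 0.44 and 0.22 for _5. Rat-GAPDH_3 differed by 0.04 against 0.54 for Rat-GAPDH_5. Rat-PGK1_5 differed by 0.44. Rat-PGK1_3 had means of 2.57 and 2.2, under the lowest detected signal of the listed probes (3.08), so its difference is not read. Without swimming hearts 14 and 15 the mean rise was 0.705, against 0.7046 with them. Training may raise these RNAs, as a hypothesis from the same data, and a difference between unrecorded batches stays open.

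Gm12665 and 1700040B14Rik belong to 29 probes bright on sedentary hearts 11, 14 and 15 alone. Sets of this kind also occur across groups: 3 of 70 trios of hearts from both groups held as many, with 57, 35 and 33 probes. All 3 trios were drawn from sedentary hearts 11 and 15 and swimming hearts 14 and 15. A split that set these hearts against the rest gave 10890 probes at an unadjusted p under 0.05 (limma). Such sets thus need no difference in training. Whether they come from RNAs that vary between hearts or from a factor shared by these arrays was not tested. A single foreign source of RNA in different amounts would keep the differences between arrays alike across the probes. Their SD was 1.12 between arrays 11 and 14, 1.03 between arrays 11 and 15 and 0.895 between arrays 14 and 15, which leaves this open.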

How the results depend on the processing

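Quantile normalization and median centring each left 987 higher and 512 lower probes. Neither could change much, since the deposited arrays already shared nearly the same distribution. The counts rose to 1572 and 953 without the lowest 30% of probes and to 2142 and 1441 without the lowest 50%, where fewer probes are tested, and to 1693 and 1363 with array weights. They fell to 3 and 2 without a trend and to 620 and 293 with a robust trend. With the replicate number as a block they were 0 and 0 in limma (7203 and 6168 at an unadjusted p under 0.05). Deviations of same-numbered hearts from their group means correlated at 0.041, 0.114, -0.087 and 0.136. The highest correlation of each sedentary heart with a differently numbered swimming heart was 0.047, 0.148, 0.099 and 0.139. Such weak correlations cannot tell whether a number marks a shared litter, cage or day. Leaving out 1 array gave 2 to 855 higher and 2 to 305 lower, and leaving out swimming arrays 14 and 15, chosen after seeing the data, gave 1310 and 1751. A difference of at least 1 on the log2 scale left 200 and 107 with adjusted p and gave 1621 and 1256 with unadjusted p. Many calls lie close to the threshold: without a trend 1381 of the 1499 had an adjusted p under 0.1, and without sedentary array 11, 795. The probes with an unadjusted p under 0.05 numbered 16323, and 12683 to 16543 with 1 array left out; the highest of the other splits drawn, which moves swimming heart 11 to the sedentary side, gave 13067. Of the authors' 128 probes, 32 passed, 81 without the lowest 30% and 83 of the 89 still tested without the lowest 50%, 57 with array weights, 1 without a trend, 0 with the block, 11 with the equal-variance test over all probes, and 0 to 17 with 1 array left out (these were chosen after seeing the data). Of 37 probes given by name or by probe ID alone, 0 changed direction. Of these, 26 were called, and 25 of them lost the call without a trend and 26 without sedentary array 11 or 14. Of the 11 not called, 9 passed without the lowest 30% of probes and 4 with array weights, and without the lowest 50% all 7 that were still tested passed. The causes were not tested. The tests of gene lists and of 1 probe per symbol were not run, since too few probes are named. Low signal over background limits the folds of probes not detected in a group.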

Other observations

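The test in this part was chosen only after the result was seen. Bright probes (mean log2 intensity 6 to 10) with IDs that begin with mmu, the class of 127 of the 128 probes in the authors' deposited table, lay lower in swimming hearts than bright probes with IDs that begin with A. Their median difference was -0.144 over 4776 probes, against 0.0228 over 11969. Per heart, the median deviation of the first class minus that of the second was 0.094 ± 0.036 (SD, n = 4) in sedentary and -0.065 ± 0.065 (SD, n = 5) in swimming hearts, lower in 5 of 5 swimming hearts (exact two-sided permutation p = 0.00794, the smallest that 126 arrangements can give). A shift of this whole class between the groups could account for at most a small part of the listed falls. The class difference was -0.159 per heart, and each listed probe differed by at least 1.2 on the log2 scale. Over mmu probes of any brightness the median difference was -0.0363, and the class holds nearly all listed rises as well. Whether the shift comes from the RNA or from labelling was not tested.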
